A study of Mus musculus with 6 samples.

How the data were processed

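Small RNA sequencing libraries came from macrophages grown out of mouse bone marrow, 3 from ApoE-knockout (EKO) and 3 from wild-type (WT) animals, and the series design states that the replicates are biological. Per the labels, marrow cells from male mice of 6 to 12 weeks were cultured in DMEM with 10% serum, M-CSF was given at 25 ng/mL every 2 days for 6 days, total RNA was purified on columns (RNeasy Mini), and libraries were made with an NEB small RNA kit. Total RNA from such columns can lose part of the small RNA fraction, and ligation and PCR in small RNA kits favour some sequences, so that levels of different miRNAs in 1 library are not on a common scale. The genome build is mm9 per the submitters' processing notes, and the aligner and counting program are not given in the sources used here.

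Each library had 1 deposited table of read counts per reference. Per the file headers, the tables hold the number of distinct read sequences, the total read count, an estimated count in which reads matching several references are divided among them, and a molecular-barcode count. The barcode count summed to 0 over all libraries, so PCR copies were not removed. An interval or floor drawn from the read counts of 1 library would thus cover counting error only. The standard errors below come from a fit that includes the spread between replicates. The estimated counts as the authors deposited them were rounded to whole numbers and used throughout, and the total read counts served as an alternative. A table lists only references with reads, so a missing reference was taken as 0. Over the 6 tables there were 911 mature miRNA references, of which 20 were joint entries of near-identical miRNAs, and 73 stem-loop references, which took 0.00127% to 0.00161% of the reads and were left out. Library totals ranged from 34651511 to 41331604 reads on mature miRNAs. Near-identical members of a family, such as those of let-7, can share reads, and their split rests on the authors' counting.

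The main comparison used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by genotype, the quasi-likelihood test (glmQLFit and glmQLFTest) on genotype alone, and a Benjamini-Hochberg adjusted p threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM, the count of a miRNA scaled to a library total of 1e+06 reads, further scaled by TMM, as mean ± SD of 3 libraries, except for sums over lists of other cell types and their members, which are plain CPM. Total reads, detected miRNAs and the share of the 10 most abundant miRNAs were compared by two-sided exact permutation tests. In all, 28 lists of miRNAs (macrophage functions, polycistronic clusters, seed families and markers of other cell types) were tested with camera (limma 3.58.1, preset correlation 0.01) where 3 or more members were tested, which held for 26, and again with an estimated correlation and with fry. The miRNAs named are 10 focus miRNAs whatever their result, the 5 most abundant, and up to 4 members per list with the smallest p. Also named are the 10 largest changes per direction past the threshold with non-overlapping groups and a mean of at least 10 CPM or, with fewer than 3 such, the 3 with the smallest p per direction. This rule, the lists, the tests and the alternatives below were fixed before the data were examined. Examples from lists were later limited to members with an unadjusted p under 0.05, and a few others named for their detection or arms were chosen after their values were seen.

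Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, total counts only, no low-count filter, at least 10 reads in every library, a mean of at least 10 CPM, the total read counts, thinning to the smallest total, leaving out the 3 most abundant miRNAs, a replicate block, and leaving out each library in turn. Combinations with the filter on mean CPM were added after seeing the data. For the GC correction, the GC content of the 5' or 3' side of the hairpin that holds each miRNA was taken from GENCODE M21 precursor transcripts of the GRCm38 assembly by name, with no coordinates used. Each library's trend with GC content, a robust local regression, was removed as an offset. Of the 251 miRNAs averaging at least 10 CPM, 235 (93.6%) had a value, and the others were given the median GC content. The fits were tested on simulated counts for this comparison, drawn for each miRNA independently from a negative binomial distribution. Changes shared across miRNAs and reads copied from few captured molecules were not simulated, so the rates in the real libraries can differ. The main fit recovered 30.6% of 183 miRNAs changed 2-fold and 52.8% of 180 changed 4-fold, and the fit restricted to a mean of at least 10 CPM recovered 66.3% of 89 and 97.9% of 94, with 1 to 4 false calls each.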

Results

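Apolipoprotein E (ApoE) is a lipid-transport protein that macrophages secrete, and the series asked how its loss alters the microRNAs (miRNAs) of cultured macrophages. Bone marrow from male ApoE-knockout (EKO) and wild-type (WT) mice aged 6 to 12 weeks was differentiated in culture with macrophage colony-stimulating factor (M-CSF, 25 ng/mL, given every 2 days over 6 days) into bone-marrow-derived macrophages. Small RNA from 3 EKO and 3 WT biological replicates was sequenced, and reads were counted on mature miRNAs. Apoe mRNA is not measured by these counts, so no value here checks the genotype labels.

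The EKO libraries held 34651511, 39532544 and 37084445 reads on mature miRNAs, and the WT libraries held 38440290, 41331604 and 40913114. The mean difference was -3138800 reads (two-sided exact permutation p = 0.2, where 3 against 3 cannot go below 0.1). The 10 most abundant miRNAs took 77.0% ± 0.211 (SD, n = 3) of the reads in EKO and 77.9% ± 0.923 (SD, n = 3) in WT (exact permutation p = 0.2). No pair of replicates of 1 genotype held alike counts, with a chi-square per degree of freedom between 222 and 1817 that sets them against read-counting error only. Their log2 CPM correlated across miRNAs with r between 0.87 and 0.88 for pairs of EKO libraries and between 0.92 and 0.94 for pairs of WT libraries.

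Fewer miRNAs were detected in the EKO libraries. The 3 EKO libraries held 543, 577 and 591 mature miRNAs with at least 1 read, and the WT libraries held 684, 664 and 698. All 3 EKO libraries lay below all 3 WT libraries (570.3 ± 24.7 against 682 ± 17.1, SD, n = 3 each). The exact permutation p of 0.1 is the smallest that the design allows. After every library had been thinned to 34651511 reads the difference was -112 miRNAs, against -111.7 before. Among the miRNAs seen almost only in WT was miR-196a-5p, encoded within the Hox clusters, at 2.10 ± 0.789 CPM in WT and 0.00878 ± 0.0152 in EKO (SD, n = 3 each). The Sfmbt2 intronic cluster's miR-669e-5p stood at 1.92 ± 0.290 CPM in WT and 0.00878 ± 0.0152 in EKO. Neither passed the test over all miRNAs (adjusted p = 0.0786 and 0.0803, edgeR quasi-likelihood test). References seen in at most 3 libraries with at least 5 reads had a median of 34.5, 34 and 27 reads in the WT libraries and 67, 50 and 49 in the EKO libraries. Levels as low as those of these 2 miRNAs may thus rest on few captured molecules. Fewer captured molecules per EKO library may also account for the lower number detected, so it cannot be read as a property of the cells. In the Sfmbt2 cluster 7 of 28 tested miRNAs had higher values in EKO, among them miR-669c-5p at 302 ± 92.0 CPM in EKO and 208 ± 25.8 in WT.

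**Figure D1:**
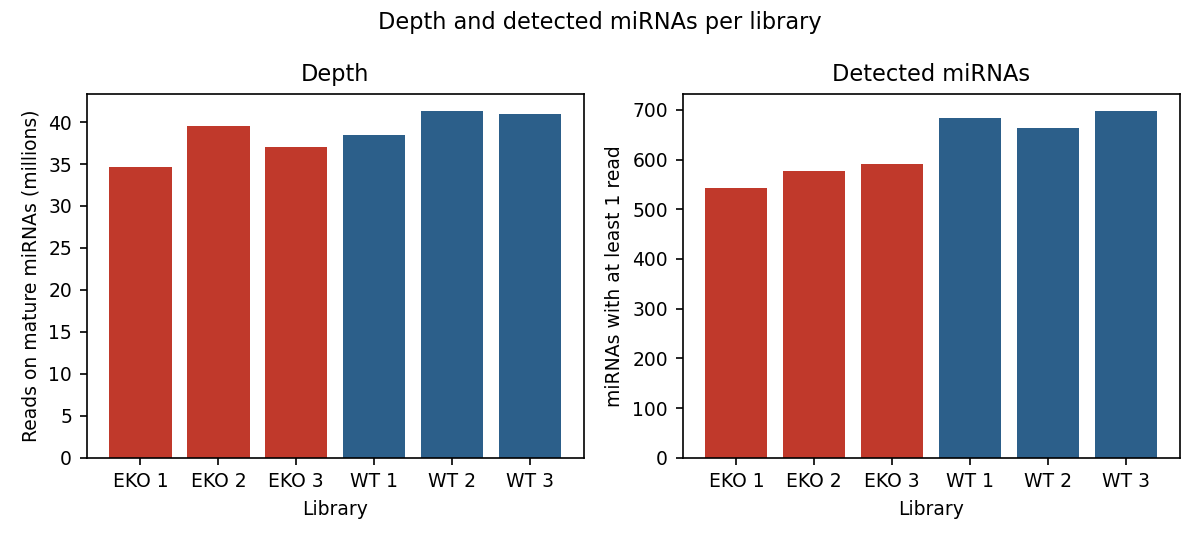
Bars give, per library, the reads on mature miRNAs (left, axis in units of 1e+06 reads) and the number of miRNAs with at least 1 read (right), for 3 EKO (red) and 3 WT (blue) libraries. Depth overlaps between the genotypes, while the EKO libraries hold 543 to 591 detected miRNAs and the WT libraries 664 to 698.

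The comparison of EKO with WT macrophages asked which miRNAs differ with ApoE deficiency. No miRNA passed an adjusted p of 0.05 among the 575 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, smallest adjusted p = 0.0766). At an unadjusted p under 0.05 there were 48 miRNAs higher and 75 lower in EKO, 123 in all where chance gives 28.8. For 180 miRNAs (31.3%) the 3 EKO and 3 WT values did not overlap, where chance gives 10%. The median log2 fold change of all tested miRNAs was -0.16, and it was -0.08 with DESeq2 size factors, -0.14 with upper-quartile factors and -0.18 with total counts only.

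The smallest p-values among miRNAs averaging at least 10 CPM belonged, on the higher side, to miR-1981-5p, miR-122-5p and miR-223-5p. The abundance of miR-1981-5p was 2905 ± 589 CPM in EKO and 1407 ± 244 in WT (SD, n = 3 each), a log2 fold change of 1.05 ± 0.19 (SE). Levels of miR-122-5p, the main miRNA of hepatocytes, were 121 ± 37.0 CPM and 51.4 ± 6.67 (log2 fold change 1.24 ± 0.25). Those of miR-223-5p, whose opposite arm is abundant in granulocytes and monocytes, were 2789 ± 104 CPM and 2024 ± 141 (log2 fold change 0.46 ± 0.10). On the lower side stood miR-19b-3p, a member of the miR-17-92 polycistron that is also encoded on chromosome X, at 22.5 ± 5.77 CPM in EKO and 68.8 ± 10.6 in WT (log2 fold change -1.61 ± 0.26). The joint entry of miR-374b-5p and miR-374c-5p, whose near-identical sequences share reads, stood at 107 ± 15.2 CPM in EKO and 227 ± 50.8 in WT (log2 fold change -1.09 ± 0.20). Also lower was miR-21a-5p, an abundant miRNA that targets the Pdcd4 transcript, at 152630 ± 7127 CPM in EKO and 215900 ± 11500 in WT (log2 fold change -0.50 ± 0.09). Each of these 6 had an adjusted p of 0.0766 (edgeR quasi-likelihood test), with all 3 EKO libraries on 1 side of all 3 WT libraries.

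The count of calls depended on the filter and the tool, from 0 to 100. DESeq2 called 49 miRNAs higher and 51 lower, limma-voom 9 and 23, and the edgeR test restricted to the 251 miRNAs averaging at least 10 CPM called 27 higher and 32 lower. All 6 miRNAs above passed under that restriction (adjusted p from 0.0228 to 0.0233). They had been picked for the smallest p among those same miRNAs in the same libraries, so this pass adds no independent support for the 6 miRNAs. Over the other settings of the analysis fixed in advance, this restriction included, their adjusted p ranged from 4.29e-05 to 0.285, with a pass in 7 settings each. The restriction was among those settings but was singled out only after the 0 calls were seen. Its 59 calls became 13 without EKO replicate 1, 1 without EKO replicate 2, 91 without EKO replicate 3, and 0 without any of the 3 WT replicates in turn. Removing each library's trend with GC content left 46 of the 59 called in the same direction. It took the log2 fold change of miR-21a-5p from -0.47 to -0.26, which no longer passed (adjusted p = 0.0808, edgeR).

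**Figure D2:**
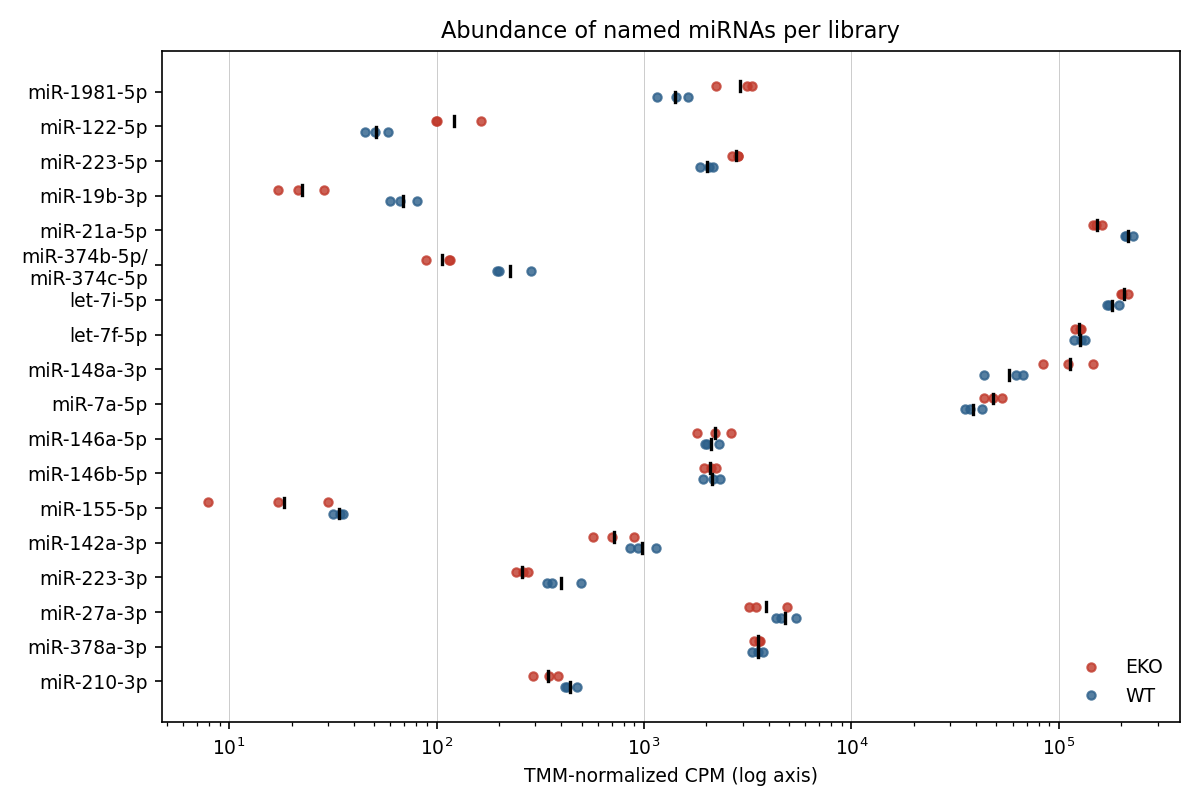
Points give the TMM-normalized CPM (log axis) of named miRNAs in 3 EKO (red) and 3 WT (blue) libraries, and black ticks give the group means. The EKO and WT points separate for miR-1981-5p, miR-122-5p and miR-223-5p (higher in EKO) and for miR-19b-3p, miR-21a-5p and miR-374b-5p/miR-374c-5p (lower), and overlap for miR-146a-5p, miR-146b-5p and miR-378a-3p.

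Among the 10 macrophage, inflammation and lipid miRNAs chosen in advance, none passed over all miRNAs, and miR-21a-5p and miR-223-3p passed when adjusted over the list alone, both lower. Levels of miR-146a-5p, which restrains Toll-like receptor signalling through Traf6 and Irak1, were 2205 ± 405 CPM in EKO and 2099 ± 184 in WT (SD, n = 3 each), a log2 fold change of 0.07 ± 0.15 (SE) that lay within the spread between replicates. Its near relative miR-146b-5p stood at 2091 ± 145 and 2138 ± 196 CPM (-0.03 ± 0.11), and miR-378a-3p, which lies within Ppargc1b, at 3538 ± 127 and 3538 ± 213 CPM. The myeloid miR-223-3p stood at 259 ± 16.2 CPM in EKO and 399 ± 84.2 in WT (-0.62 ± 0.17, adjusted p = 0.0848, edgeR), the opposite side from miR-223-5p of the same precursor. The haematopoietic miR-142a-3p stood at 720 ± 165 and 980 ± 148 CPM (-0.45 ± 0.19). The hypoxia-induced miR-210-3p stood at 343 ± 47.4 and 441 ± 32.4 CPM (-0.36 ± 0.14), and miR-27a-3p at 3863 ± 900 and 4772 ± 546 CPM (-0.30 ± 0.17). Counts of miR-155-5p, a Toll-like receptor-induced miRNA, were low, at 18.4 ± 11.1 CPM in EKO and 33.8 ± 1.95 in WT (-0.88 ± 0.44, adjusted p = 0.323, edgeR). The Srebf2-encoded miR-33-5p, which targets the cholesterol exporter ABCA1, was close to the detection limit, at 0.092, 0 and 0 CPM in EKO and 0.903, 0.671 and 0.42 in WT.

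The most abundant miRNA was let-7i-5p in all 3 EKO libraries and miR-21a-5p in all 3 WT libraries. Levels of let-7i-5p were 205710 ± 9073 CPM in EKO and 180500 ± 13402 in WT (SD, n = 3 each), a log2 fold change of 0.19 ± 0.09 (SE, adjusted p = 0.306, edgeR quasi-likelihood test). By the mean over all 6 libraries, after these 2 followed let-7f-5p, at 124890 ± 4099 and 126530 ± 8274 CPM (-0.02 ± 0.09). Then came miR-148a-3p, which targets the transcripts of the LDL receptor and ABCA1, at 113740 ± 31221 CPM in EKO and 57549 ± 12379 in WT (0.98 ± 0.23, adjusted p = 0.0766), and miR-7a-5p, at 48329 ± 4563 and 38491 ± 3736 CPM (0.33 ± 0.11, adjusted p = 0.138). The mean of miR-148a-3p in EKO was 1.98-fold that in WT, and that of miR-21a-5p in WT was 1.41-fold that in EKO.

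Of the 26 miRNA lists that could be tested, 4 were called, all lower in EKO (camera with a preset correlation of 0.01): energy metabolism and hypoxia, cholesterol efflux and lipid handling, promotion of macrophage inflammation, and the miR-17-92 cluster. With an estimated correlation no list was called (adjusted p = 0.380 for each of the 4). No member of these lists passed over all miRNAs. The lower direction was not particular to the 4 lists. Camera gave it, mostly far from the threshold, for every tested list but the erythroid, the epithelial, and the muscle, neuron, liver and endocrine lists. Restraint of NF-kB and Toll-like receptor signalling, opposite in function to promotion of inflammation, also had 12 of 14 members lower (camera adjusted p = 0.0828). For energy metabolism and hypoxia, 11 of 12 tested miRNAs had lower values in EKO, with miR-378a-3p at a log2 fold change of 0 among them. Of these, 6 passed when adjusted over the list alone (median log2 fold change -0.69, camera adjusted p = 0.00413). Its members with the smallest p were miR-30c-5p, at 702 ± 163 CPM in EKO and 1329 ± 250 in WT, miR-143-3p, at 90.4 ± 28.1 and 186 ± 29.6 CPM, and miR-103-3p, a regulator of insulin signalling, at 599 ± 83.6 and 986 ± 200 CPM (SD, n = 3 each). For cholesterol efflux and lipid handling, 18 of 21 miRNAs had lower values (16 with DESeq2 size factors or upper-quartile factors). Adjusted over the list alone, 10 passed lower and 1 higher, miR-148a-3p (median -0.57, camera adjusted p = 0.00764). Besides miR-19b-3p and miR-30c-5p, which targets the transcript of the microsomal triglyceride transfer protein, this list held miR-23a-3p, at 416 ± 114 CPM in EKO and 856 ± 185 in WT. For promotion of macrophage inflammation, 12 of 14 miRNAs had lower values. Adjusted over the list alone, 6 passed lower and 1 higher, miR-342-5p (median -0.62, camera adjusted p = 0.0170). Its miR-125b-5p stood at 154 ± 14.5 and 241 ± 16.4 CPM, and miR-27b-3p at 15969 ± 1817 and 22452 ± 2538 CPM. For the miR-17-92 cluster, a polycistron that supports proliferation, 9 of 10 miRNAs had lower values and 3 passed adjusted over the list alone (median -0.96, camera adjusted p = 0.0211). Its miR-17-5p stood at 232 ± 77.5 CPM in EKO and 495 ± 102 in WT, and its miR-20a-5p at 327 ± 134 and 661 ± 209 CPM. By replicate, miR-17-5p was at 167, 210 and 318 CPM in EKO and 455, 418 and 611 in WT, and miR-20a-5p at 212, 294 and 474, and 533, 549 and 902. Both were highest in replicate 3 of each genotype, which had the lowest median reads on references seen in at most 3 libraries (49 in EKO, 27 in WT). This did not hold in both genotypes for miR-19b-3p or miR-18a-3p. Counts of miR-19b-3p and miR-92a-3p are not of this cluster alone, since both are also encoded on chromosome X.

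The 4 lists overlapped, with 11 of their 43 distinct tested miRNAs in more than 1 list. With GC content removed among miRNAs averaging at least 10 CPM none was called (adjusted p = 0.0866 for each). That correction, chosen after seeing the data, took the list medians from -0.63, -0.50, -0.61 and -0.87 to -0.52, -0.41, -0.59 and -0.65. Without EKO replicate 2 only the energy metabolism list was called. Without WT replicate 1 the inflammation list and the miR-17-92 cluster were lost (adjusted p = 0.0605 for each), and the miR-17-92 cluster was also lost without EKO replicate 1, WT replicate 2 or WT replicate 3 (adjusted p from 0.0516 to 0.0662) and with limma-voom on all libraries (adjusted p = 0.0639).

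**Figure D3:**
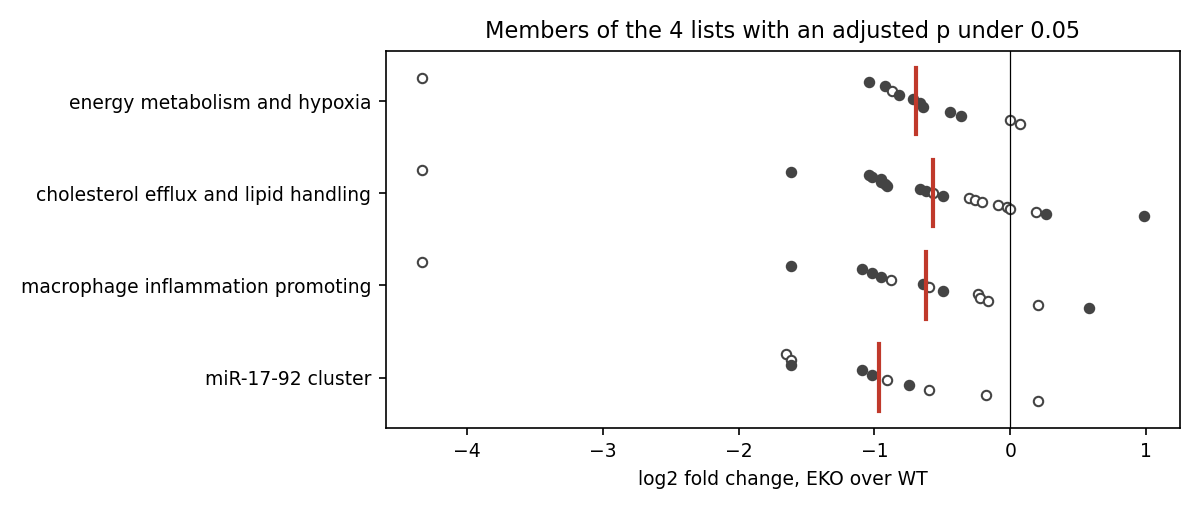
Each point is a tested miRNA of the 4 called lists, placed at its log2 fold change of EKO over WT, filled where its unadjusted p was under 0.05, and the red bar is the list median. The medians lie at -0.69, -0.57, -0.62 and -0.96, and the outlying point near -4.33 in 3 lists is miR-33-5p, which had almost no reads in EKO.

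Lists of miRNAs of other cell types that a marrow culture could hold were tested in the same way, and none was called (smallest camera adjusted p = 0.0678). The summed level of 5 lymphoid-enriched miRNAs, such as miR-181b-5p, was 548 ± 53.4 CPM in EKO and 728 ± 63.5 in WT (SD, n = 3 each, exact permutation p = 0.1). The summed level of erythroid miRNAs, mainly miR-486a-5p/miR-486b-5p, was 145 ± 24 and 151 ± 22.1 CPM (exact p = 0.7). By member, 2 of 3 tested had higher values in EKO (median log2 fold change 0.64, camera adjusted p = 0.3). Among them was miR-451a, at 5.92, 5.31 and 1.29 CPM in EKO and 0, 0 and 0.587 in WT (log2 fold change 4.49 ± 2.03, adjusted p = 0.26, edgeR). Stromal fibroblast miRNAs summed to 4173 ± 124 and 4379 ± 79.9 CPM (exact p = 0.2), carried by miR-140-3p, at 3680 ± 159 and 3559 ± 75.3 CPM. By member, 5 of 7 tested stromal miRNAs had lower values in EKO (median log2 fold change -0.87, camera adjusted p = 0.122, fry adjusted p = 0.00109), with 2 past the threshold adjusted over the list alone. Among them were miR-143-3p, also in the energy metabolism list, at 88.7 ± 22.8 and 187 ± 22.9 CPM, and miR-140-5p, at 175 ± 59.6 and 324 ± 70.0 CPM. Epithelial miRNAs summed to 150 ± 33.4 and 152 ± 6.45 CPM (exact p = 1). The list of stem, progenitor, megakaryocyte and endothelial miRNAs reached 31644 ± 1181 CPM in EKO and 26567 ± 1318 in WT (exact p = 0.1), carried by miR-10a-5p, at 18698 ± 2642 and 12688 ± 1588 CPM. By member, 5 of 7 tested had lower values in EKO (4 with DESeq2 size factors), with a median log2 fold change of -0.16 and a mean of -1.50 (camera adjusted p = 0.468, fry adjusted p = 0.0136). Adjusted over the list alone, miR-10a-5p passed higher, and miR-125b-5p and miR-196a-5p passed lower. The list of muscle, neuron, liver and endocrine miRNAs reached 132 ± 29.6 and 55.4 ± 7.96 CPM (exact p = 0.1), nearly all of it miR-122-5p. This list was called higher with no low-count filter (adjusted p = 0.0472) and without EKO replicate 3 (adjusted p = 0.0355). The granulocyte pair miR-223-3p and miR-223-5p, too small a list for the test, summed to 3018 ± 122 and 2447 ± 80.7 CPM (exact p = 0.1). The higher sum was carried by miR-223-5p, at 2761 ± 107 and 2042 ± 106 CPM, while miR-223-3p stood at 257 ± 27.6 and 405 ± 99.6 CPM.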

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

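The combinations with the filter on a mean of at least 10 CPM and the adjustment over those miRNAs alone were chosen only after the results were seen. The calls per miRNA depended on the test and on the low-count filter. Where the main fit called 0 miRNAs higher and 0 lower in EKO, DESeq2 called 49 and 51 (212 miRNAs without an adjusted p), limma-voom 9 and 23, no low-count filter 24 and 28, at least 10 reads in every library 21 and 22, and a mean of at least 10 CPM 27 and 32. DESeq2 size factors, upper-quartile factors, total counts only, the total read counts, thinning, and leaving out the 3 most abundant miRNAs each gave 0 and 0. With a mean of at least 10 CPM, the calls were 32 and 22 after GC correction, 26 and 30 with limma-voom and 44 and 39 with DESeq2. Part of the gain came from testing fewer miRNAs, since the main p-values adjusted over those 251 alone gave 44 calls against 59 when refitted; the cause of the rest was not tested. Leaving out each library in turn gave 0 to 38 higher and 0 to 53 lower, both filters included. Under the main filter 16 and 29 were called without EKO replicate 3 and none without any other library.

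The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.10, -0.04 and -0.02, and no EKO library correlated best with the WT library of its own number. With the number as a replicate block 26 miRNAs were higher and 36 lower, and with a mean of at least 10 CPM and the replicate block 41 and 54.

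The 4 lists called became 0 with an estimated correlation, 15 with fry (which does not compare a list with other miRNAs), 0 with a mean of at least 10 CPM and GC correction, and 2 with that filter and the replicate block; leaving out each library gave 1 to 6 under the main filter and 0 to 4 with a mean of at least 10 CPM. Over 17 refits fixed in advance the energy metabolism list was called in 17, the cholesterol list in 16, the inflammation list in 15 and the miR-17-92 cluster in 11. Without EKO replicate 3 the 10 focus miRNAs were also called lower (adjusted p = 0.0355).

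Fewer detected miRNAs in EKO, the lower total of reads and the lower share of the 10 most abundant kept their direction under each alternative run. Of the named miRNAs, the values close to 0 changed sign in places, never past the threshold. With other scaling factors the median log2 fold change of all tested miRNAs moved too, from -0.1604 to -0.0757 with DESeq2 size factors and to -0.1351 with upper-quartile factors. Sign changes under those factors thus went with a shift of all tested miRNAs, and the cause of the others was not tested. The log2 fold change of miR-378a-3p, which is 0 to 4 decimals in the main fit, was 0.0841 with DESeq2, 0.002 with limma-voom, 0.0842 with DESeq2 size factors, 0.0248 with upper-quartile factors, 0.0285 with no filter, 0.0506 with at least 10 reads in every library, 0.0324 with a mean of at least 10 CPM, 0.0473 with the total read counts, 0.0173 after thinning, 0.029 without the 3 most abundant miRNAs and 0.0011 with the replicate block. With a mean of at least 10 CPM it was 0.0859 after GC correction, 0.0321 with the replicate block, 0.0329 with limma-voom and 0.0814 with DESeq2, and with each library left out it ran from -0.036 to 0.0817. The log2 fold change of let-7f-5p (-0.02) was 0.065 with DESeq2, 0.0651 with DESeq2 size factors, 0.0049 with upper-quartile factors, 0.0095 with no filter, 0.0313 with at least 10 reads in every library, 0.013 with a mean of at least 10 CPM and 0.0271 with the total read counts. With that mean filter it was 0.3267 after GC correction, 0.0138 with the replicate block, 0.0147 with limma-voom and 0.0624 with DESeq2, and it ran from -0.0583 to 0.06 with each library left out. The hairpin sides of let-7f-5p hold 38.8% GC on average, against a median of 50%. The log2 fold change of miR-146b-5p (-0.03) was 0.0506 with DESeq2, 0.0508 with DESeq2 size factors, 0.0175 with at least 10 reads in every library and 0.0136 with the total read counts, then with the mean filter 0.0814 after GC correction, 0.001 with the replicate block, 0.0033 with limma-voom and 0.0479 with DESeq2, and from -0.0892 to 0.0666 with each library left out. The log2 fold change of miR-146a-5p (0.07) ran from -0.0699 to 0.2387 with each library left out and was below 0 only without EKO replicate 3.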

Other observations

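The comparison of the arms of each precursor, the sum over miRNAs averaging under 1 CPM, the GC-corrected fit and the other combinations with a mean of at least 10 CPM were chosen only after the results were seen. Among lists not described above, none was called (camera adjusted p from 0.0828 to 0.995). In the let-7 family 8 of 11 tested members had lower values in EKO (7 of 11 with DESeq2 size factors or upper-quartile factors), and 4 passed when adjusted over the list alone: let-7e-5p, at 557 ± 99.4 CPM in EKO and 895 ± 32.8 in WT (SD, n = 3 each), let-7g-5p, let-7d-5p and miR-98-5p. The miR-221-222 cluster, which represses the cell-cycle inhibitor p27, had 2 of 4 members lower (1 of 4 with DESeq2 size factors), with miR-221-3p at 2947 ± 865 and 6498 ± 1621 CPM (adjusted p = 0.0766, edgeR quasi-likelihood test). In the miR-106b-25 cluster 4 of 6 members were lower, led by miR-93-5p at 406 ± 53.4 and 683 ± 122 CPM. For restraint of NF-kB and Toll-like receptor signalling 12 of 14 members were lower (10 with DESeq2 size factors), among them miR-125a-5p at 119 ± 55.5 and 341 ± 77.1 CPM. For alternative activation 7 of 10 were lower (6 with DESeq2 size factors or upper-quartile factors, 8 with total counts only). For the p53 response 6 of 7 were lower, among them miR-34a-5p at 18.3 ± 1.06 and 35.4 ± 10.8 CPM. The imprinted Dlk1-Dio3 cluster, with 1 member tested, summed to 0.237 CPM in EKO and 2.33 in WT, levels that may rest on few captured molecules.

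Arms of 1 precursor are counted separately, and the difference between them was not tested. For miR-223, the 5p arm was higher and the 3p arm lower in EKO (log2 fold change 0.49 and -0.59, both past the threshold among miRNAs averaging at least 10 CPM), and for miR-221 the values were 0.12 for 5p and -1.11 for 3p. Of 53 precursors with both arms averaging at least 10 CPM, 24 had an arm past that threshold, and miR-223 was the only precursor with both.

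For the calls, the 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The 0 calls of the main fit were met by 10 of the 10 splits, with 0 as the highest of the others. The real split was the only 1 of the 10 to reach its value for unadjusted p under 0.05 (123, highest other 36), for calls among miRNAs averaging at least 10 CPM (59, highest other 0) and for miRNA lists called (4, highest other 1).

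Fewer miRNAs were detected in EKO libraries, and sequencing depth is argued against, since thinning to the smallest total left 1.003 of the difference. Fewer captured molecules per EKO library may account for it: references seen in at most 3 libraries with at least 5 reads had a median of 67, 50 and 49 reads in EKO and 34.5, 34 and 27 in WT. The WT libraries thinned to the molecule number this gives for EKO detected 606, 578 and 581 miRNAs. Their mean of 588 lay within the EKO range of 543 to 591 but above the EKO mean of 570.3, and WT replicate 1 lay above that range. As the molecule number itself rests on rarely seen references, it is not independent of the difference in detection. Less RNA of low-abundance miRNAs stays open: the summed CPM of the 660 miRNAs averaging under 10 CPM in EKO was 0.935 of that in WT, but even losing all of the 412 averaging under 1 CPM would have left 0.855, above the bound of 0.8 set for this test, which therefore decides nothing. Those 412 summed to 101 ± 14 CPM in EKO and 155 ± 18.6 in WT (SD, n = 3 each, exact permutation p = 0.1), and as a miRNA that fewer molecules leave undetected also enters such a set, this sum does not separate the explanations. Whether fewer molecules reflect RNA input, library preparation or less miRNA per EKO cell stays open too, since each is confounded with genotype here.

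The EKO minus WT differences of abundant miRNAs have several candidate explanations. The log2 fold changes followed GC content across 235 miRNAs, which are not independent replicates (Spearman 0.256, permutation p = 8e-05). Levels were taken relative to each miRNA's mean over the 6 libraries. Their slope on GC content was positive in the EKO libraries (0.178, 0.056 and 0.040 log2 units per 10 GC points) and negative in the WT libraries (-0.067, -0.065 and -0.143). Since these slopes are relative to that mean, they show a difference between the genotypes and not which of them carries a GC trend of its own. Median GC content was 54.5% among calls higher and 46.3% among calls lower in EKO. Removing the trend kept 46 of the 59 calls, and the median absolute log2 fold change over all 59 was 0.79 before and after. This argues against GC-dependent capture or amplification as the whole cause. It holds only as far as the GC content of a hairpin side, taken by name, measures that bias, and a part left uncorrected is not excluded. The arms of 53 precursors did not move together, as their log2 fold changes were uncorrelated (r = 0.025, 95% bootstrap interval -0.21 to 0.27), with the same sign in 29. For the 16 precursors left at a cut of 100 CPM, r was -0.35, which leans to opposed arms. A change in the amount of the precursors was thus not seen as a shared shift of both arms. It is not excluded, since a library bias that differs between arms could hide such a shift. The differences may lie on an axis that also separates replicates of 1 genotype: ordered by reads per rare reference, differences between replicates correlated across 251 miRNAs with the genotype difference from the remaining libraries, at a median r of 0.392 (from 0.0081 to 0.58 over 6 pairs). An effect of ApoE deficiency on processing or stability of single arms stays open and was not tested.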
